A study of Danio rerio with 6 samples.

How the data were processed

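Gene expression was measured in whole brains of 6 male zebrafish of the AB strain at 12 months of age, with 1 brain per sample. Per the labels, 3 fish came from embryos kept in water with 100 ppb lead as lead acetate from before 2 hours to 72 hours after fertilization, and 3 came from embryos kept at 0 ppb. All fish were reared at 28 °C and had no lead in the water after the embryonic exposure. Total RNA was turned into cDNA, labelled with Cy3 and hybridised to 1-colour NimbleGen oligonucleotide arrays, with 1 array per brain. Female brains are part of the study's design and were not analysed here.

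Each array has a deposited table of intensity values on a linear scale, 1 for each target sequence. The values were made with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of each target. The deposited series value table holds the intensity of single probes, whose sorted values were almost the same in all 6 columns, and 27114 of its 140663 probes had random sequences that target no gene. The other 113549 probes belonged to 38489 target sequences, of which 36632 had 3 probes, 1796 had 2 and 61 had 1. The deposited list of altered probes gives log2 expression ratios of lead-exposed over control and a p-value per probe, with the test not given in the sources used here. A first sheet of that list held the same probes and values as the second and was not used.

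The log2 of each deposited RMA intensity was taken, and 1 control row was left out, which left 38489 transcripts. No filter on dim transcripts was applied. Target sequences were named through the annotation in the array files, written for the Zv7 assembly, and updated through a table of current zebrafish gene names. Of the 3055 RefSeq accessions on the array 2663 matched that table. The file's own symbol was current for 4820 other targets, was updated through synonyms for 5753 and was kept as given for 3028. A map marker and a homologue name together named 681 more. In all, 16945 targets had a zebrafish symbol, for 12350 different symbols, 6519 had only the name of a homologue in another species, and 15025 had no name. Coordinates are those of Zv7 in the array files. Targets on the reverse strand of an annotated transcript numbered 1380.

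Lead-exposed and control brains were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, 2-sided, on all 6 arrays with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all transcripts, with a threshold of 0.05. A looser set took transcripts at unadjusted p under 0.05 with a fold of at least 1.5. Log2 fold changes are lead-exposed minus control, and errors are limma's standard errors unless given as SD. With 3 arrays against 3, an exact permutation test of a single value cannot give p below 0.1, and the number of arrays limits the precision of every value. The labels give 1 fish per sample but do not say whether fish of a group shared a tank, so p-values measure the spread between these fish. Control arrays took the first 3 positions of the scan and lead-exposed arrays the last 3, so position and group cannot be told apart. The image names of replicate 1 of each group lacked a prefix that the other 4 had, and this was treated as a possible batch.

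Lists of genes were tested with limma's camera at a preset correlation of 0.01 between genes, on 1 transcript per gene, the brightest over all 6 arrays. There were 37 lists, each with at least 5 measured genes, and p-values were adjusted over the lists. They covered transmitters and synapses, cell types of the brain and of neighbouring tissues, brain regions, metal handling, haem synthesis, hormones, chromatin, cell division, cancer genes, immune response and housekeeping complexes, among others. A total of 44 genes stood in more than 1 list. Camera with a correlation estimated for each list, and limma's fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run as alternatives. The comparison, the lists, the alternatives apart from those named in the closing section and the rule for naming genes were fixed before the data were examined.

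The rule named up to 14 genes per direction. As no transcript passed the adjusted threshold, these were the smallest unadjusted p-values among transcripts with a fold of at least 1.5, groups that did not overlap and a mean in the higher group above the 25th percentile of all values. There were 453 such transcripts with higher and 253 with lower values. Transcripts without a symbol or with a clone-type symbol were passed over, 20 before the last named higher gene and 33 before the last named lower gene. The rule also took up to 4 members with the smallest p of each list described, 18 genes fixed in advance because of their link to lead or to the brain, not all of which are reported here, and the 8 named genes with the largest listed change in each direction in the authors' deposited table. Other genes named in the text were chosen after their values were seen.

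The statistics were tested on simulated arrays with the real means of all 38489 transcripts, in which 200 transcripts were changed, 50 at each fold. Their spreads were limma's moderated variances, which are drawn toward a common value. The shares recovered may therefore be higher than the real spreads would give. Of those changed 1.5-fold 0% passed the adjusted threshold, of those changed 2-fold 28%, of those changed 3-fold 82% and of those changed 4-fold 96%. At unadjusted p under 0.05 with a 1.5-fold change the shares recovered were 50%, 94%, 100% and 100%. A simulated list of 50 genes shifted by 0.3 log2 had an adjusted p of 5.77e-17 in camera, and an unshifted list had 0.772. The simulated transcripts varied independently of each other, so the list test was not tried on genes that move together. Correlations estimated in real lists were 0.024 for the cell cycle, 0.395 for astroglia, 0.135 for telencephalon and 0.562 for ribosomal proteins, against the preset 0.01.

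As a check on background, the random-sequence probes of the series value table were put through the same comparison. Alternatives used the series value table averaged per target, a repeated quantile normalization, median centring, the replicate number or the image name prefix as a block, array weights, removal of each array in turn, removal of the dimmer 50% of transcripts, an intensity trend with a robust prior, other thresholds, 1 value per gene, single probes, and other settings of the list tests. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.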

Results

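The data were 6 one-colour arrays, 3 of control and 3 of lead-exposed male zebrafish brains at 12 months of age, and each array measured 38489 transcripts. The fish had met lead only as embryos, so the comparison asks which transcripts of the aged brain differ long after an early exposure to 100 ppb. Median log2 values of the arrays lay between 10.96 and 11.02. The random-sequence probes, which measure background, had medians between 7.97 and 8.12 and 95th percentiles between 10.41 and 10.91. Between 50.6% and 58.3% of the transcripts of an array were above that 95th percentile.

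The arrays did not separate by exposure. The mean Pearson correlation across transcripts was 0.976 within groups and 0.976 between groups, and single pairs ranged from 0.969 to 0.987. The first principal component held 40.6% of the variance and placed control 3, at 24.2, on the side of lead-exposed 1 and 3, at 39.1 and 49.4. Lead-exposed 2, at −37.6, lay with controls 1 and 2, at −38.1 and −37.0. On the second component, with 19.8% of the variance, control 3 stood apart at −56.6.

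**Figure D1:**
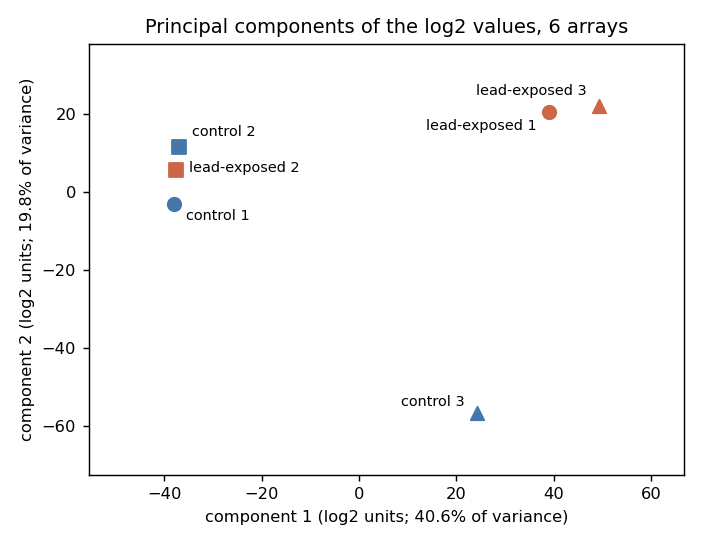
Scores of the 6 arrays on the first and second principal components of the log2 values, in log2 units, with control arrays in blue, lead-exposed arrays in orange and a symbol for each replicate. Lead-exposed 2 sits with controls 1 and 2 near −37, and control 3 sits at 24.2 on the first component and −56.6 on the second.

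The transcripts with the smallest p-values in lead-exposed brains were higher for spice1, a centriole and spindle protein, and for pdx1, a pancreatic and duodenal homeobox factor. Values of spice1, on chromosome 24 at 19921215 to 19931856 of Zv7, were 9.24 ± 0.08 in controls and 10.60 ± 0.20 in exposed brains (log2, SD, n = 3), a difference of 1.36 (SE 0.14). Values of pdx1, on chromosome 24 at 16237858 to 16240375, were 10.26 ± 0.32 and 11.99 ± 0.27, a difference of 1.73 (SE 0.21) that was 0.96 with the series value table averaged per target. The steroid dehydrogenase gene hsd17b2 differed by 1.17 (SE 0.17), the mitotic kinesin gene kif20a by 0.78 (SE 0.12) and the interleukin 17 family gene il17a/f3 by 0.99 (SE 0.17). Further higher values were those of gbgt1l3 (0.90), gpd1 (0.81), FBN3 (0.79), ralba (0.77), runx2a (0.75), TGM1 (0.74), slc9a3.2 (0.72), ablim3 (0.67) and tbc1d22a (0.64). None of these 14 genes passed the adjusted threshold in limma, each with an adjusted p of 0.568.

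Among the 14 genes with lower values was flt4, the receptor of lymphatic and venous endothelium, at 12.22 ± 0.16 in controls and 11.41 ± 0.14 in exposed brains (log2, SD, n = 3), a difference of −0.81 (SE 0.14). The transporter gene slc22a6l differed by −1.39 (SE 0.31), gc2 by −1.14 (SE 0.26), the corepressor gene tle5 by −0.87 (SE 0.19) and the hair cell factor gene pou4f3 by −0.81 (SE 0.15). Differences were −0.80 for bag2, a chaperone cofactor, −0.74 for mst1, −0.72 for ap1s1, −0.70 for the muscle gene mybpc1 and −0.68 for utp25, the last −0.43 with the series value table. They were −0.66 for KCNJ2, a potassium channel gene, −0.66 for the muscle caveolin gene cav3, −0.63 for rassf4a and −0.59 for golph3l. Each had an adjusted p of 0.568 in limma, so none passed. Other transcripts of some of these genes gave other values, with a difference of 0.38 for a second cav3 transcript, 0.00 for a second FBN3 transcript, −0.02 and −0.04 for others of tbc1d22a, 0.23 for a second of runx2a and −0.11 for a second of bag2. They were −0.28 for a second of ap1s1, −0.16 and −0.39 for others of mybpc1, −0.38 for a second of golph3l and between −0.15 and 0.29 for the others of ablim3.

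**Figure D2:**
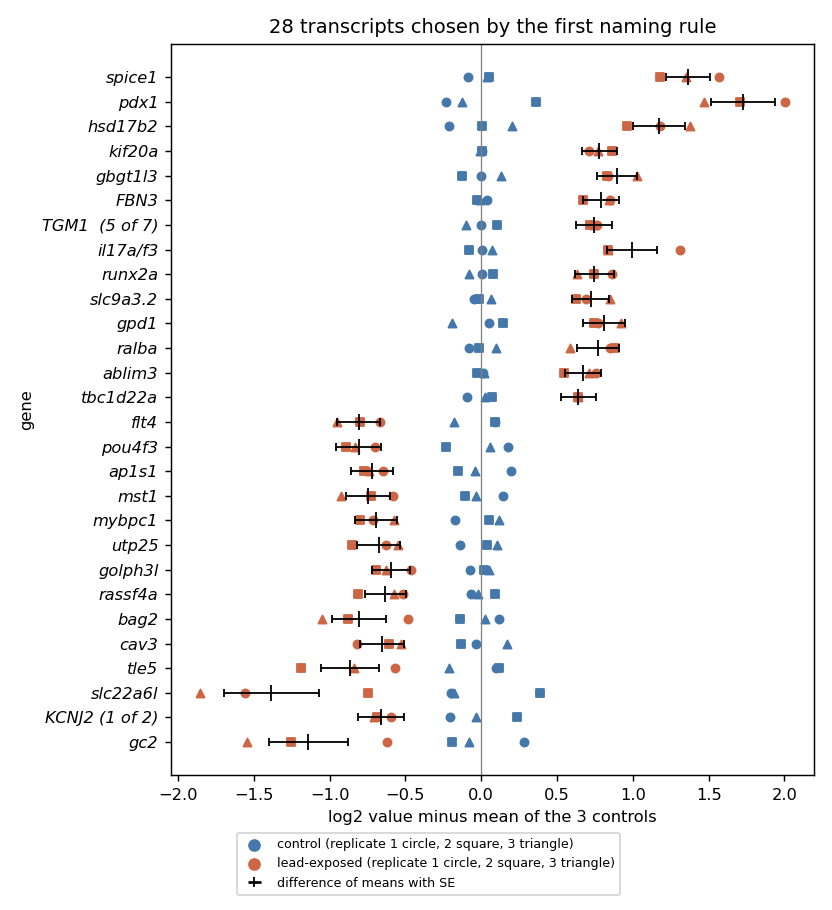
Log2 values of 28 transcripts on each array, minus the mean of the 3 controls, with controls in blue and lead-exposed arrays in orange, and the difference of group means with its standard error in black. The groups of these transcripts do not overlap because the rule that named them required it, and the differences run from −1.39 for slc22a6l to 1.73 for pdx1, which differed by 0.96 with the series value table.

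Over all 38489 transcripts, 0 passed the adjusted threshold in limma, with a smallest adjusted p of 0.568, and an unpaired equal-variance test on the same values also gave 0. At unadjusted p under 0.05 there were 2768 transcripts, 1613 higher and 1155 lower in lead-exposed brains, against 1924 by chance. With a fold of at least 1.5 there were 998, of which 611 were higher and 387 lower, and 416 of them had a zebrafish symbol. The groups did not overlap for 5042 transcripts, or 13.1%, where chance gives 10%. Without lead-exposed 2 the 998 became 2541, without control 3 they became 1566, and with array weights 2340. With the image name prefix as a block they were 973. On the 4 arrays with the prefix alone, 0 transcripts passed the adjusted threshold in limma. There 1203 were at unadjusted p under 0.05, fewer than the 1924 by chance, and 969 also had the fold. The 2 arrays without it allow no test.

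The random-sequence probes, which target no gene, also differed between the groups. Of these 27114 probes 23.2% were at unadjusted p under 0.05 and 15.3% also had a fold of at least 1.5, with 0 past the adjusted threshold in limma and a smallest adjusted p of 0.0704. At unadjusted p under 0.05 more of them were lower in exposed arrays (3537) than higher (2761), while dim target probes were more often higher (4299) than lower (3752). With each array centred on the mean of the random-sequence probes, 3446 of them were lower and 3162 higher. Target probes no brighter than the 95th percentile of random-sequence probes met both limits in 11.6% of cases, and brighter ones in 3.11%. Most of the named differences lay in that range, since 721 of the 998 transcripts and 23 of the 28 genes named above had a mean at or below the random-sequence limit. Both flt4 and tle5 were above it on all 6 arrays, while spice1 was above it on 2 arrays and hsd17b2 and kif20a on 0. Of list members given below, lhx8a, aldoca, chrm5a, adra2da, cldn5b, kcnj8, bace2, suv39h1a, kita and cyp19a1a were above it on 0 arrays. Others, among them top2a, slc6a9, dlx2a and cp, were above it on all 6. Position in the scan and exposure cannot be told apart on these arrays.

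**Figure D3:**
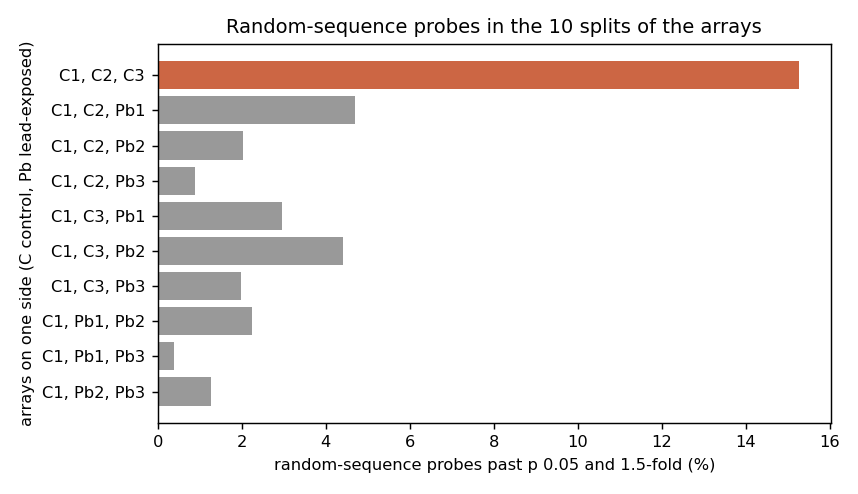
Percentage of random-sequence probes past unadjusted p 0.05 and a 1.5-fold difference when the 6 arrays are split into 3 and 3 in each of the 10 possible ways, with C for control and Pb for lead-exposed. The split by exposure, in orange, gives 15.3%, and the highest of the others gives 4.7%.

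Genes of the cell cycle were higher in lead-exposed brains as a group. Of 57 measured members 42 were higher and 15 lower, with a median log2 difference of 0.17. The mitotic genes kif20a (0.78), ube2c (0.85) and tpx2 (0.61) and the topoisomerase gene top2a (0.81) had the smallest p-values. Values of top2a were 11.96 ± 0.14 in controls and 12.78 ± 0.22 in exposed brains (log2, SD, n = 3). The difference was 0.53 with the series value table, and other top2a targets differed by 0.08 to 1.07. Reverse-strand targets among them differed by 0.73 and 0.71, and their forward partners by 1.07 and 0.40. At unadjusted p under 0.05 there were 10 higher members and 1 lower, the lower one being ascl1a (−0.44), a factor of neuronal progenitors. Genes of DNA replication went both ways, with pcna (−0.13), mcm5 (−0.17) and rfc5 (−0.17) lower. Among them mcm3 (0.05), mcm10 (0.19) and pola1 (0.24) were higher. No member passed the threshold over all transcripts, and 4 passed when adjusted over the list alone. The list rose in camera with an adjusted p of 1.2e-05, which was lost with an adjusted p = 0.52 with an estimated correlation. The correlation estimated for it was 0.024, near the preset 0.01. For acetylcholine signalling the estimate was −0.026, below the preset, and the unadjusted p in camera still rose from 0.143 to 0.199. The loss therefore does not by itself show that cell cycle genes move together. Means of the cell cycle list were above 0 on each exposed array (0.14, 0.04 and 0.12) and below 0 on each control array (−0.08, −0.07 and −0.16). The group difference of the list was 0.22 log2 on the arrays without the image name prefix and 0.19 on those with it. The random-sequence probes also differed by this grouping of the arrays, more often lower than higher (3446 against 3162 with the arrays centred). On average 32 of the 57 members lay at or below the 95th percentile of these probes.

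Markers of astroglia and radial glia were lower in lead-exposed brains, for 23 of 26 measured members, with a median of −0.29. The members with the smallest p-values were the glycine transporter gene slc6a9 (−0.63, SE 0.24), ptgdsb.1 (−0.39, SE 0.18), the bicarbonate transporter gene slc4a4a (−0.42, SE 0.20) and aldoca (−0.46, SE 0.21), which the cerebellum list also holds. Values were −0.20 for aldoca with the series value table, −0.25 for ptgdsb.1 without lead-exposed 1 and −0.75 for a second slc6a9 transcript. The glial filament gene gfap differed by 0.02 (SE 0.20). A single member was at unadjusted p under 0.05, and 0 passed in limma, both over all transcripts and when adjusted over the list alone. The list fell in camera with an adjusted p of 0.000123, lost with an adjusted p = 0.929 with an estimated correlation. Without lead-exposed 3 the adjusted p was 0.052. List means were 0.26, 0.18 and 0.05 in the controls, −0.27 and −0.44 in lead-exposed 1 and 3, and 0.22 in lead-exposed 2, the array that lay with controls 1 and 2 on the first component. The group difference was −0.54 on the arrays without the image name prefix and −0.22 on those with it.

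Markers of the telencephalon, the forebrain region of pallium and subpallium, were lower for 15 of 19 measured members, with a median of −0.40. The homeobox genes dlx2a (−0.43, SE 0.18), nkx2.1 (−0.40, SE 0.17), lhx8a (−0.81, SE 0.37) and emx2 (−0.79, SE 0.37) had the smallest p-values. Leaving out 1 array gave −0.28 for dlx2a without lead-exposed 3, −0.36 for emx2 without lead-exposed 1 and −1.25 for lhx8a without lead-exposed 2, and lhx8a was −0.36 with the series value table and −1.23 in a second transcript. In limma 0 members were past the threshold over all transcripts, when adjusted over the list alone, or at unadjusted p under 0.05. The list fell in camera with an adjusted p of 0.00685, lost with an adjusted p = 0.929 with an estimated correlation. The call was also lost without control 2, at 0.0572, without lead-exposed 1, at 0.051, and with the dimmer 50% of transcripts left out, at 0.0568. A second list of 14 other telencephalon genes, chosen after the results were seen, had 7 members higher and 7 lower, with a median of 0.01 and a mean of −0.006, and an adjusted p of 0.887 in camera in place of the first list. Means of the first list were 0.21, 0.38 and 0.01 in controls, −0.51 and −0.26 in lead-exposed 1 and 3, and 0.18 in lead-exposed 2, which lay with controls 1 and 2 on the first component. Over the 6 arrays these means went with those of ribosomal proteins (Pearson's r = 0.891, Spearman's rho = 0.771, permutation p of 0.015 and 0.103) and of astroglia (r = 0.868, rho = 0.771, permutation p of 0.031 and 0.103). Without the 2 arrays farthest from the median r was 0.764 and 0.583, and after adjustment over 5 relations the p for r was 0.075 and 0.078. With the second telencephalon list r was 0.66, rho 0.714 and the permutation p 0.165 and 0.136, and r was 0.795 without the 2 farthest. With microglia r was 0.621 (permutation p of 0.189) and 0.273 without the 2 farthest. With the cell cycle r was −0.693 (permutation p of 0.131) and turned to 0.411 without them. Astroglia and ribosomal proteins had been called lower by exposure as well, so part of their agreement with the first list was given in advance. The sets of 4 and 2 arrays with and without the prefix are too small for a correlation within each. The group difference was −0.72 on the arrays without the image name prefix and −0.23 on those with it.

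Ribosomal protein genes were lower for 43 of 51 measured members, by a small amount, with a median of −0.09. Examples were rpl23 (−0.22), rpl5a (−0.22), rpl9 (−0.21) and rpl3 (−0.18). Without lead-exposed 3 these 4 lay between −0.14 and −0.10, and without lead-exposed 2 the first 3 lay between −0.37 and −0.33. With the series value table rpl23 was −0.05, with array weights rpl9 was −0.32, other rpl9 transcripts differed by −0.19 to 0.47 and a second of rpl3 by 0.18. In limma 0 members were past the threshold over all transcripts, when adjusted over the list alone, or at unadjusted p under 0.05. The list fell in camera with an adjusted p of 0.0384, lost with an adjusted p = 0.929 with an estimated correlation. The call was also lost with the image name prefix as a block (0.0673), with a repeated quantile normalization (0.122), with the mean of all transcripts of a gene (0.107), and without control 1 (0.307), control 2 (0.11), lead-exposed 1 (0.254) or lead-exposed 3 (0.32). List means were 0.11 in lead-exposed 2, −0.11 and −0.14 in lead-exposed 1 and 3, and 0.09, 0.09 and −0.05 in controls. The group difference was −0.20 on the arrays without the prefix and −0.03 on those with it.

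**Figure D4:**
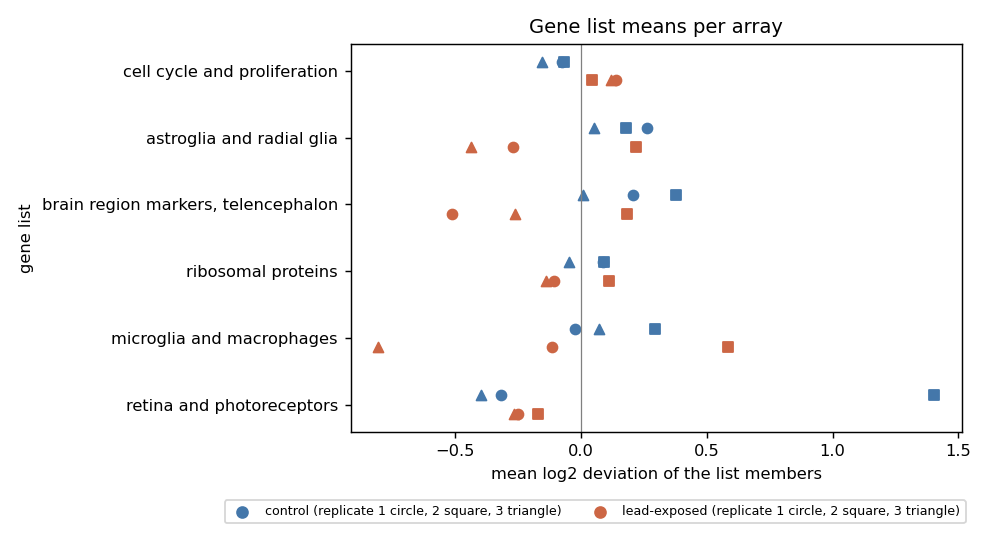
Mean log2 deviation of the members of 6 gene lists on each array from the gene's mean over all arrays, with controls in blue, lead-exposed arrays in orange and a symbol for each replicate. Cell cycle means lie on opposite sides of 0 in the groups, from −0.16 to −0.07 in controls and from 0.04 to 0.14 in exposed arrays, while lead-exposed 2 lies among or above the controls for astroglia and ribosomal proteins.

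In all, 4 of the 37 lists passed in camera, 0 with an estimated correlation and 0 with fry. Testing for changes in either direction, a test chosen after the results were seen, fry gave 3, namely the cell cycle (adjusted p of 9.76e-05), skeletal muscle (0.0161) and vascular and mural cells (0.0461).

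Vascular and mural cell genes went both ways, with 18 of 25 members higher and 7 lower. Values of flt4 (−0.81) and of the pericyte gene rgs5a (−0.71) were lower and were the 2 members that passed when adjusted over the list alone, with none past the threshold over all transcripts in limma and 6 at unadjusted p under 0.05. The endothelial tight junction gene cldn5b (0.39) was higher and the channel gene kcnj8 (−0.54) was lower, with −0.34 in the series value table and −0.35 without lead-exposed 1. The list as a whole did not pass in camera, at an adjusted p of 0.24.

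Lists of genes tied to known targets of lead did not pass in camera before a setting was changed. For metal handling and oxidative stress 34 of 46 members were lower, with a median of −0.11 and an adjusted p of 0.24 in camera (0.0424 without lead-exposed 2), while hmox1b (0.46), a haem oxygenase, and slc39a14 (0.57), a metal transporter, were higher and cp (−1.19), the ceruloplasmin gene, was lower. The metallothionein gene mt2 was 13.97 ± 0.31 in controls and 12.86 ± 0.93 in exposed brains (log2, SD, n = 3), a difference of −1.11 (SE 0.45) that was −0.72 without lead-exposed 3. Other transcripts differed by −1.28 and −1.29 for cp and by 0.19 and −0.25 for slc39a14. For haem synthesis 7 members were higher and 8 lower, at an adjusted p of 0.887, and the homologue of ALAD, the lead-sensitive enzyme of that pathway, differed by −0.07 (SE 0.18). Monoamine genes were higher for 19 of 27 members, at an adjusted p of 0.0932. This list passed, higher, with the series value table (0.0434), array weights (0.0287), the dimmer 50% of transcripts left out (0.0125) and without lead-exposed 2 (0.00246). It also passed with transcripts above the random-sequence range, a test chosen after the results were seen (0.0309), and over all alternatives its adjusted p reached 0.929. Among its members, nr4a2b (0.53), drd4a (0.46) and drd3 (0.34) were higher and adra2da (−0.53) was lower. Without lead-exposed 1 drd4a was 0.30, and other nr4a2b transcripts differed by 0.14 and −0.06. The tyrosine hydroxylase gene th differed by 0.07 (SE 0.19).

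Adjusted p-values in camera were 0.385 for GABA signalling, 0.887 for glutamate receptors and transport, 0.364 for acetylcholine signalling and 0.392 for synaptic vesicle release. The GABA synthesis genes gad1b (−0.11, SE 0.12) and gad2 (−0.08, SE 0.13), the vesicle fusion gene snap25a (−0.05, SE 0.11) and the neurotrophin gene bdnf (0.14, SE 0.15) differed by less than 1 standard error. The nicotinic receptor gene chrna5 (0.44) and the muscarinic genes chrm2a (0.57) and chrm5a (0.54) were higher in the acetylcholine list. In the list of axon guidance and neurotrophins, which had 0.887, ngfra (0.62) and sema3d (0.63) were higher and tenm3 (−0.60) and robo4 (−0.55) lower. A second tenm3 transcript differed by −0.34, and robo4 was −0.34 without lead-exposed 1. Values were 0.36 for chrm2a without lead-exposed 1 and 0.33 for chrm5a with the series value table, and second transcripts differed by 0.46 for ngfra and −0.45 for gad1b. None of these genes passed in limma.

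For amyloid and tau related genes 11 of 18 members were lower, at an adjusted p of 0.391 in camera. The apolipoprotein gene apoeb differed by −0.74 (SE 0.28), with groups that did not overlap, bace2 by −0.51, clu by −0.21 and bace1 by 0.36, and none passed in limma. Other transcripts of apoeb differed by −0.13 and −0.36. Without lead-exposed 3 apoeb was −0.47 and bace1 0.18, and without control 1 bace1 was 0.21. Values of the amyloid precursor gene appa differed by −0.06 (SE 0.12), less than 1 standard error. Hormone genes had adjusted p-values of 0.712 for steroid and thyroid signalling, 0.329 for hypothalamic and other neuropeptides and 0.93 for pituitary hormones. The ovarian-type aromatase gene cyp19a1a (0.96) was higher and hsd20b2 (−0.65) lower, while the brain aromatase gene cyp19a1b (−0.33, SE 0.24) and the glucocorticoid receptor gene nr3c1 (0.01, SE 0.12) had groups that overlapped. Values of cyp19a1a were above the random-sequence limit on 0 arrays and those of hsd20b2 on 1. A second transcript differed by 0.43 for cyp19a1a and by 0.28 for nr3c1, hsd20b2 was −0.26 without lead-exposed 3, and cyp19a1b ran from −0.52 without control 2 to −0.14 without control 3. Among the neuropeptides spx was higher (0.67) and cart2 (−0.88), gnrh3 (−0.77) and uts1 (−0.65) were lower, with 0 members past the threshold in limma and 2 at unadjusted p under 0.05. Values were 0.43 for spx with the series value table, −0.41 for cart2 without lead-exposed 1 and −0.36 for gnrh3 without control 2.

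DNA methylation and chromatin enzymes were higher for 20 of 34 members, at an adjusted p of 0.0932 in camera. The list passed, higher, with array weights (0.0296), the mean of all transcripts of a gene (0.0323), without control 3 (0.0403) and without lead-exposed 2 (0.0166), in a range up to 0.929. The maintenance methyltransferase gene dnmt1 differed by 0.34 (SE 0.16), hdac8 by 0.34 (SE 0.12), suv39h1a by 0.40 and kat2b by 0.52, and none passed in limma. They were 0.17 for dnmt1 with the series value table and 0.24 for kat2b without control 2. Oncogenes and tumour suppressors were higher for 44 of 72 members, at an adjusted p of 0.887, with the growth factor receptor genes pdgfra (−0.94) and kita (−0.53), the Wnt pathway gene axin2 (−0.89) and ptenb (−0.41) all lower. A second transcript differed by −0.64 for pdgfra and 0.06 for kita, kita was −0.28 with the series value table, and axin2 was −0.59 without lead-exposed 1. Genes of meninges and connective tissue had an adjusted p of 0.224, and 0.0487 with array weights and 0.0224 without control 3, with the sulfate transporter gene slc13a4 (−1.65), the matrix gene mgp (−0.51) and krt8 (−0.50) lower. A second slc13a4 transcript differed by −2.78, and mgp was −0.33 with the series value table.

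The other lists did not pass in camera either before a setting was changed. Adjusted p-values were 0.16 for microglia and macrophages, 0.364 for neutrophils and lymphocytes, 0.998 for interferon and inflammatory response, 0.43 for erythrocytes, 0.93 for oligodendrocyte and myelin, 0.712 for neuronal pan markers and 0.364 for cilia and ependyma. They were 0.93 for midbrain and hindbrain, 0.43 for cerebellum, 0.965 for habenula and pineal, 0.364 for immediate early genes and 0.887 for the circadian clock. They were 0.364 for chaperones and the unfolded protein response, 0.24 for oxidative phosphorylation, 0.368 for the proteasome and 0.998 for skeletal muscle. Some passed, all lower but immediate early genes, when 1 setting was changed. Without lead-exposed 2 the adjusted p was 1.21e-05 for microglia and macrophages, 0.00248 for oxidative phosphorylation, 0.0046 for the proteasome and 0.0176 for immediate early genes. With array weights it was 0.0287 for microglia and 0.0216 for oxidative phosphorylation, and without control 2 it was 0.0441 for oxidative phosphorylation and 0.0348 for cilia and ependyma. The myelin gene mbpa differed by −0.08 (SE 0.13). The median, the mean and the direction of the test differed in sign for 5 lists, which were midbrain and hindbrain, glutamate, interferon, oligodendrocyte and skeletal muscle.

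Photoreceptor genes set control 2 apart. The medium-wave cone opsin gene opn1mw2 was 14.33 in control 2 and at most 8.25 on the other arrays (log2), and the rod opsin gene rho was 15.01 against at most 10.33. The cone opsin genes opn1sw1 and opn1sw2 were higher in control 2 than the mean of the other arrays by 5.16 and 4.55, and the retinoid carrier gene rbp3 by 4.47. Of 50 measured members of the retina list 27 were over 1 log2 higher in control 2. For lead-exposed against control 37 members were lower and 13 higher, at an adjusted p of 0.0813 in camera. The list passed, lower, with the series value table (0.0434), the mean of transcripts (0.0323), ranks (0.0355), without control 1 (0.000431) and without control 3 (0.000771), and went the other way without control 2 (0.154). The list mean of control 2 was 1.40, and the other arrays lay between −0.40 and −0.17.

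**Figure D5:**
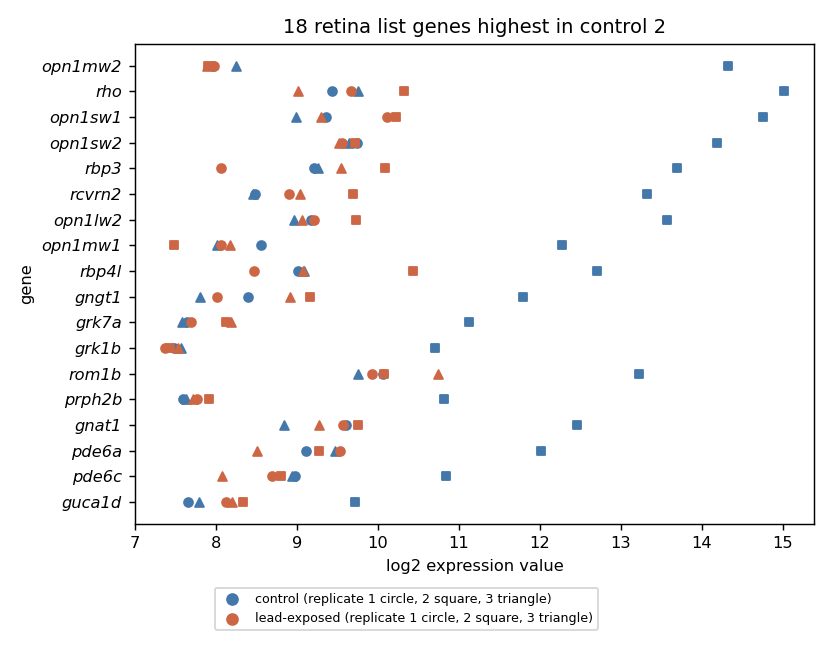
Log2 expression values of the 18 genes of the retina list with the largest excess in control 2, with a point for each array, controls in blue and lead-exposed arrays in orange. The blue square of control 2 lies to the right of all other points for each gene, at 14.33 against at most 8.25 for opn1mw2.

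The authors' deposited table lists 180 probes as altered, 90 higher and 90 lower, with folds of at least 1.5 and a largest p of 0.0498. All 180 had the same direction here, and the log2 ratios differed by at most 0.000922. The listed p-values were those of an unpaired equal-variance test on the same values, within 9.8e-05, and that test with a 1.5-fold limit gave 588 transcripts, 367 higher and 221 lower. In limma all 180 were at unadjusted p under 0.05 and 0 passed over all transcripts. Adjusted over the list alone 180 passed, which is not independent evidence because the list was chosen on these samples. Of the 180 transcripts 129 had a mean at or below the 95th percentile of the random-sequence probes.

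By the authors' names, the largest increases in their deposited table after PDX1 (1.73) were SV2C (1.39), a synaptic vesicle protein, SPICE1 (1.36), HSD17B2 (1.17), the potassium channel gene KCNK3 (1.15), PHF10 (1.14), PDE1A (1.03) and the tight junction gene OCLN (1.02). The largest decreases were those of the collagen gene COL16A1 (−1.57), SERPINF1 (−1.53), GUCY2C (−1.29), the corneal proteoglycan gene KERA (−1.08), PRKRIR (−1.02), the lens factor gene FOXE3 (−1.0), TRPC6 (−0.98) and the Wnt inhibitor gene SFRP1 (−0.96). In limma sv2ca had a difference of 1.39 (SE 0.30) and foxe3 one of −1.0 (SE 0.27), and both were above the random-sequence range on all 6 arrays. With the series value table foxe3 was −0.44, and without lead-exposed 3 SFRP1 was −0.64. All 5 transcripts of pde1a were higher, by 0.06 to 1.03, while a second transcript of phf10 differed by 0.21 and a second of kera by −0.13.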

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

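The tests with transcripts above the random-sequence range, with homologue names in the lists, with a second list of telencephalon genes and with the either-direction form of fry were chosen after the results were seen. Over the 13 alternative settings run on single genes, 0 values of the 110 named genes passed the adjusted threshold, and 8 of 1430 such values reversed, in 4 genes. Of the 99 with a value over 1 standard error, 15 moved by over 1.5 times with the series value table averaged per target, 25 with 1 array left out and 1 under another setting. With the series value table gfap was −0.020, and with array weights −0.10. Leaving out 1 array at a time, gfap ranged from −0.13 to 0.18, th from −0.082 to 0.26, the ALAD homologue from −0.19 to 0.12 and nr3c1 from −0.044 to 0.050. Of 625 results of uncalled lists 63 had the other direction, and 12 such lists passed under at least 1 setting, 30 times in all.

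The cell cycle list kept its direction and its call under every setting except an estimated correlation (0.52) and fry (0.245), with adjusted p from 3.13e-06 to 0.00165 when 1 array was left out. Estimated correlation and fry each gave 0 lists, where camera gave 4. With fry the adjusted p was 0.811 for astroglia, 0.811 for telencephalon and 0.88 for ribosomal proteins, and with an estimated correlation 0.929 for all 3. In the either-direction form these were 0.715, 0.766 and 0.767. Ribosomal proteins were lost with a repeated quantile normalization (0.122), the image name prefix as a block (0.0673) and the mean of transcripts (0.107). Leaving out 1 array gave 2 to 11 lists, with adjusted p from 1.47e-07 to 0.052 for astroglia, 0.000375 to 0.0572 for telencephalon and 0.000113 to 0.32 for ribosomal proteins. With the second list of telencephalon genes in place of the first, camera gave an adjusted p of 0.887 and the other direction for it, and 2 lists passed. Ribosomal proteins lost their call there because their rank in the adjustment over lists changed. Their own unadjusted p of 0.00415 in camera did not depend on the other list. The cause of the other changes was not tested.

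Transcripts past unadjusted p 0.05 and 1.5-fold numbered 2340 (1370 higher, 970 lower) with array weights, which gave 9 lists. Leaving out 1 array gave 852 to 2541, with 515 to 1312 higher and 337 to 1229 lower. The higher share was 61.2%, and 51.6% without lead-exposed 2. With the dimmer 50% left out there were 207 (131 higher, 76 lower), 38 of the authors' probes remained in the test, and telencephalon was at 0.0568. With transcripts above the random-sequence range on average there were 281 (175 and 106), 51 of the authors' probes stayed in the test, and 5 lists passed, among them the 4. Both counts were lower because the transcripts left out held 795 and 721 of the 998, more than their share of all transcripts. The cause of the changes in lists was not tested. With no fold limit there were 2768 (1613 and 1155), with a 2-fold limit 107 (55 and 52), with 1 value per gene 265 (152 and 113), and with single probes 7932 (4433 and 3499), of which 1 passed the adjusted threshold. That probe, named after its value was seen, targets hnmt, a histamine methyltransferase gene, and differed by −3.28 (SE 0.134), while the hnmt transcript differed by −0.08.

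Deviations of same-numbered replicates from their group means correlated at −0.148, 0.142 and 0.263 for pairs 1, 2 and 3, and 3 of 6 samples correlated best with their own number, so the numbers were not taken to pair the fish. With the replicate block 0 transcripts passed in limma, 3009 were at unadjusted p under 0.05, 1204 met both limits and 7 lists passed, among them monoamine signalling (0.0482), retina (0.0114) and microglia (0.0477). Signal over background limits these values, since 721 of the 998 transcripts had a mean at or below the random-sequence limit.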

Other observations

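The tests of background on the transcripts and on both parts of the cell cycle list, of the main axis, of the pineal organ and whole eyes, and of other splits for counts of transcripts and for single lists were chosen after the results were seen.

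Microglia and macrophage genes differed most between the 3 lead-exposed fish. The list mean was 0.58 in lead-exposed 2 and −0.81 in lead-exposed 3, and between −0.12 and 0.29 on the other arrays. The complement gene c1qa deviated from its mean over the arrays by 1.1 in lead-exposed 2 and by −2.32 in lead-exposed 3, and the macrophage gene mpeg1.1 was at 1.48 and −1.91. Proteasome genes had means of 0.23 and −0.26 on the same arrays.

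Clock genes stood apart in lead-exposed 3, with a list mean of 0.41 against −0.22 to 0.05 on the other arrays. The highest there were per1a at 2.34, ciarta at 2.23, per3 at 2.1 and nr1d1 at 1.72, while the period genes per1b and per2 were at 0.84 and 0.73. Not all members rose in lead-exposed 3, where rorcb was at −1.87, bmal2 at −1.01, rorca at −0.93 and nfil3 at −0.70. Control 3 shared part of this pattern, with rorcb at −1.54, bmal2 at −0.93, nfil3 at −0.35, per3 at 1.015 and per2 at 0.55. It did not share the rest, with per1a at −0.19, nr1d1 at −0.10, ciarta at 0.11 and rorca at 0.31. Erythrocyte genes had their highest mean in control 3, at 0.48, with alas2 at 1.19 and epb41b at 1.62, and their lowest in lead-exposed 3, at −0.35.

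The set of 998 transcripts past unadjusted p 0.05 and 1.5-fold was weighed against background. Random-sequence probes met both limits in 15.26% of cases, above the 11.62% of target probes in their range, and in the other 9 splits of the arrays they did so in at most 4.7%. Background hybridization that differs with position in the scan is therefore a candidate source of part of the differences among dim transcripts. The balance of directions was not shared, since random-sequence probes at unadjusted p under 0.05 were more often lower (3537 against 2761) and dim target probes more often higher (4299 against 3752). With each array centred on the mean of the random-sequence probes, 3446 of them were lower and 3162 higher, so part of their imbalance was an offset between arrays. For brighter probes 6.7% were at unadjusted p under 0.05, above the 5% of chance and below the 15.9% of dim probes, and background and exposure cannot be told apart there. An effect of lead on dim transcripts stays open, since position and exposure coincide.

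The cell cycle list, higher in lead-exposed brains, was weighed against 3 technical explanations. Medians of 10000 random lists of the same intensity lay between −0.087 and 0.092 in 95% of cases. The median of the cell cycle list, 0.174, stood at percentile 99.99 of them, which argues against a shift shared by such genes. Camera had picked the list on these arrays by a like comparison, so the percentiles here are not new evidence for it. The random lists also did not keep any correlation between members, and camera with an estimated correlation gave an adjusted p of 0.52. That correlation was estimated at 0.024, near the preset 0.01, so the higher p does not by itself show that members move together. With the first component in the model the median difference was 0.20 and its percentile 100, which argues against the main axis of the arrays as the whole cause. The 25 members above the random-sequence range had a median of 0.142, at percentile 99.15 of random lists of the same intensity. This sets them apart from other genes and not from random-sequence probes, so it does not decide on background. The 32 others had a median of 0.226, at percentile 100 of 10000 sets of random-sequence probes of the same level. Medians of those sets lay between −0.186 and 0.087 in 95% of cases. The sets were averages of single probes from the series value table and the members had RMA values, so this comparison does not exclude background. An effect of lead may underlie the shift, and background and position in the scan remain open as well.

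Photoreceptor transcripts in control 2 may come from retinal tissue carried along in the dissection. A second list of 9 inner retina genes had a median excess of 0.438 in control 2, at percentile 99.96 of matched random lists. The opsins rho, opn1sw1, opn1sw2, opn1mw1 and opn1mw2, which the pineal organ does not use, had a median excess of 5.16, which argues against pineal photoreceptors alone. These opsins are among the genes that had set control 2 apart, and opn1mw3 (0.09) and opn1mw4 (−0.23) had no such excess. On the other arrays they were within the random-sequence range, so the size of their excess is not exact. Lens genes had a median excess of 0.172, which argues against whole eyes. A list of 6 pigment epithelium genes had 0.081. A difference of this fish's own brain was not tested.

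Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. By exposure 0 transcripts passed the adjusted threshold in limma (2768 at unadjusted p under 0.05), and the highest other split gave 866. A count of 0 is matched by all 10 splits whatever the data, so this comparison decides nothing. For transcripts past unadjusted p and 1.5-fold the values were 998 and 3320, with 2 of 10 splits as high, and for lists 4 and 12, with 10 of 10. The cell cycle list, at an adjusted p of 1.2e-05 by exposure, also passed in 2 of the other 9 splits, with a smallest of 0.00158, so 1 of 10 splits was as small. Telencephalon, at 0.00685, passed in 2 others with a smallest of 0.0102, again 1 of 10. Astroglia, at 0.000123, passed in 3 others with a smallest of 2.76e-06, and 3 of 10 splits were as small. Ribosomal proteins, at 0.0384, passed in 3 others with a smallest of 4.61e-06, and 4 of 10 were as small. The split with 866 and 3320 set controls 1 and 2 and lead-exposed 2 against the rest, which points to a structure of the samples along the first component.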
